A study of Drosophila melanogaster with 2 samples.

How the data were processed

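The data come from a transcription factor ChIP-seq experiment on whole Drosophila melanogaster embryos aged 0 to 24 hours. The flies carried Onecut, a transcription factor with a cut domain and a homeodomain, fused to enhanced green fluorescent protein (eGFP), and chromatin was precipitated with an antibody against GFP. Chromatin was fragmented by sonication, with a size range of 200 to 800, per the labels. The 2 libraries are labelled as biological replicates 1 and 2 and form 1 group, so the design holds no comparison between conditions.

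What was used here are lists of peaks in dm6 coordinates. For each replicate alone, for both replicates together and for the pooled data there is a list of all ranked peaks and a list cut at a threshold on the irreproducible discovery rate (IDR), which measures how well the rank of a peak is kept between 2 inputs. Per the file headers, which are read-me texts beside the lists, the lists were made from the alignments of the replicates and a control alignment. The aligner, the peak caller, their versions and the read depth are not given in the sources used here, so the depth behind each peak is unknown. Signal tracks that those texts also name were not analysed here. The height of each peak is the deposited signal value, on a scale that is not given, and it was used to describe, rank, split or compare peaks only within 1 list; the 1 test of its height compared ribosomal protein promoters with other promoters by 10000 permutations, chosen after seeing the data. The deposited score of each peak is its scaled IDR, as the authors' files give it. The ranked lists also hold the deposited -log10 of the IDR, and the lowest value in each thresholded list was 2.00, an IDR of 0.01. A few ranked peaks past that value were not in the thresholded lists, between 8 and 18 per list, for a reason not given. For the ranked list of both replicates the authors' files give the signal of each peak in both inputs, in columns without names, so neither column was assigned to a numbered replicate.

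The main list was the conservative one, made from the 2 biological replicates. Its 6755 peaks include 8 outside chromosome arms 2L, 2R, 3L, 3R, 4 and X, which were left out of all steps that use the genome. Sequence was taken from the Release 6 assembly and genes from Ensembl release 115, both in the coordinates of dm6, and all peaks on the arms ended within the arm lengths. A summit is the position of highest signal that the list gives for a peak. Summits were assigned in this order: promoter (within 500 bp of a transcription start site, TSS, of a protein-coding gene), 5' UTR, coding exon, 3' UTR, intron, and other, which is all remaining sequence. The shares were compared with 1000 shuffles of positions within arms (permutation test, two-sided).

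Motifs were searched on both strands of 101 bp windows centred on summits. The control windows lay 500 to 1500 bp away on either side, in no peak of the same list. They could lie in ranked peaks below the threshold or, for shorter lists, in peaks left out of the list. Fisher's exact test, two-sided, was run for 12 motifs and then for all 2080 6-mers with reverse complements joined. A 6-mer was counted with an adjusted p under 0.05 and an odds ratio over 1.5. For 16 gene lists, genes with at least 1 summit from 1000 bp upstream to the gene's end were compared with all protein-coding genes by Fisher's exact test, two-sided, and with 10000 draws of genes matched on length in 20 bins. Density per arm was tested with 10000 draws of uniform positions. The stronger and weaker 25% of peaks were compared by Fisher's exact test. Genes for tRNA, snRNA, snoRNA, rRNA and miRNA were counted within 250 bp of a summit against 1000 shuffles. Overlap between the replicates' own lists needed 1 bp and was compared with 1000 shuffles, one-sided. P-values called adjusted were adjusted by the Benjamini-Hochberg method within each family of tests. The others, such as those of replicate overlap and of signal at ribosomal protein promoters, are unadjusted. Peaks, windows and genes are not biological replicates: these p-values and the 95% Wilson intervals describe the lists at hand and not the spread between embryo collections. Some of the odds ratios had p-values too small for the computer's number format, and only their intervals are given.

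Genes were named by a rule fixed before the data were examined, as were the lists, motifs and tests: the tagged gene; the protein-coding gene with the nearest TSS to each of the 20 peaks of highest signal; of each gene list with an adjusted p under 0.05 the 4 members with the highest peak, and of each other list the 2 members; and the 5 protein-coding genes with most summits. By its annotated symbol the germ line list also holds Nos, nitric oxide synthase, which had no summit. Of the alternatives tried, most were fixed at the same time: the pooled list, each replicate's list alone, the stronger 50% of peaks, other promoter windows (250 and 1000 bp), other motif windows (51 and 201 bp), control windows matched on GC content and on distance to the TSS, dinucleotide-shuffled windows, other ways to assign peaks to genes, and other overlap rules. A stricter IDR of 0.001, sub-threshold summits of the ranked list as the control, a background of genes with any ranked peak, and 20 gene families picked by symbol were chosen after seeing the data. So were the signal of unshared peaks, the motif by genomic class, peak width and distance from the summit, the removal of windows with TATCGATA or CGATA, the counts at ribosomal protein promoters and the sequence that follows the motif. The plan asked for an IDR of 0.01 as the stricter setting where a list gives the IDR; the thresholded lists give it only in scaled form, as the score, and already stop there, so that setting could remove nothing, and the stronger 50% of peaks, which the plan named for lists without an IDR, was used in its place.

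The tests of location, motifs, 6-mers, gene lists, overlap, non-coding RNA genes, arm density and strong against weak peaks were run on simulated data. With 30% of 6747 summits planted at promoters the location step returned a promoter share of 37.9%, against 38.0% built in, and it called 0 classes in 10 sets of uniform positions. These location runs used 200 shuffles, too few for 1 class alone to pass after adjustment. The count of 0 therefore does not measure false calls of lone classes. Writing ATCGAT into 10% of 6746 random windows raised its share by 9.68 percentage points and put it at rank 1 of 2080 6-mers; with nothing planted, 0 motifs and 0 6-mers were called. With uniform summits, Fisher's exact test called 9 of the 16 gene lists, since long genes catch more summits, and the length-matched test called 0. When every one of 92 genes in a list was given a summit, both tests called it. For 70.0% of peaks kept with small shifts, the overlap step returned 70.9%. The non-coding RNA step called 0 of 5 classes with nothing planted and called tRNA genes when summits were planted at 20 of them. A first run of that step with 200 shuffles did not call the planted genes, because the smallest adjusted p was then 0.05, so the step was run with 1000 shuffles, as in the main analysis. With uniform positions 0 arms were called and the X ratio was 1.04; with 20% of X summits taken away it was 0.833 and was called. Strong against weak peaks gave 0 calls with random signal, and the promoter share was called when promoter summits were given a signal 2 times as high. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.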

Results

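Onecut was mapped in 2 biological replicates of whole embryos collected from 0 to 24 hours of development, a span that takes in every stage of embryogenesis and all embryonic tissues. Replicate 1 alone gave 5133 peaks past the authors' threshold and replicate 2 alone gave 6023, a ratio of 1.17. The list made from both replicates held 6755 peaks and the list from pooled data held 7222, a ratio of 1.07. These were drawn from ranked lists of 31012, 38160, 32412 and 33286 peaks. The median peak of the main list was 436 bp wide and had a signal of 148.9, with the middle 50% of peaks between 106.3 and 246.7. The read depth behind these lists is unknown.

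The replicates marked largely shared sites. Of the 5115 peaks of replicate 1 on the chromosome arms, 4195 overlapped a peak of replicate 2 (82.0%, 95% Wilson interval 80.9 to 83.0), against a mean of 2.82% for shuffled peaks. Of the 6017 peaks of replicate 2, 4292 overlapped a peak of replicate 1 (71.3%, 70.2 to 72.5), against 2.44%. The one-sided permutation p was 0.001 in both directions, the smallest that 1000 shuffles can give. Unshared peaks were weaker: in replicate 1 their median signal was 55.4, against 93.2 for shared peaks, and in replicate 2 it was 66.8 against 116.1. Most of them overlapped a peak of lower rank in the other replicate's ranked list: 816 of 920 for replicate 1 and 1585 of 1725 for replicate 2. No shuffled level was computed for this overlap. The ranked lists, with 31012 and 38160 peaks for replicates 1 and 2, allow more overlap by chance than the thresholded lists. Of the 6755 peaks of the main list, 4200 (62.2%) overlapped a thresholded peak in the list of each replicate. Across the 32412 ranked peaks, the signal in the 2 inputs had a Spearman rho of 0.655 and a Pearson r of 0.922. These correlations are across peaks, which are not independent replicates.

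Onecut summits lay mainly at promoters and in introns and were nearly absent from coding sequence. Of the 6747 summits on the arms, 2980 (44.2%) fell within 500 bp of the TSS of a protein-coding gene, against 11.5% ± 0.387 (SD over 1000 shuffles), a 3.85-fold excess. Coding exons held 32 summits (0.474%, against 13.9%) and 3' UTRs held 73 (1.08%, against 4.48%). Introns held 2513 summits (37.2%), slightly below their shuffled share of 39.3%, and sequence outside protein-coding genes held 1082 (16.0%, against 30.0%). Each of these 5 classes had an adjusted p of 0.0024, from the smallest permutation p that 1000 two-sided shuffles allow. 5' UTRs beyond the promoter window held 67 summits (0.993%, against 0.788%; permutation test, adjusted p = 0.0659). This class passed the permutation test without replicate 1 (1.44-fold, adjusted p = 0.008) and with a 250 bp promoter (1.71-fold, adjusted p = 0.0024), and it passed as a deficit with a 1000 bp promoter (0.614-fold, adjusted p = 0.026). The intron share moved to a slight excess, 1.03-fold, when the promoter window was 250 bp.

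**Figure D1:**
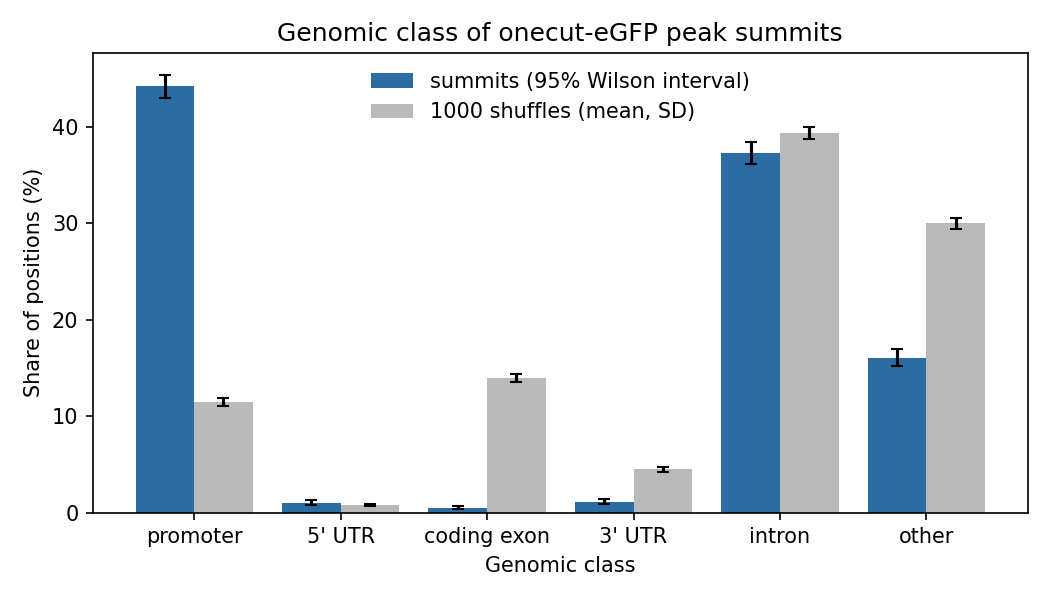
Share of the 6747 summits in each genomic class (blue, with 95% Wilson intervals) beside the mean of 1000 shuffles within chromosome arms (grey, with SD), in percent. Promoters hold 44.2% of summits against 11.5% of shuffled positions, and coding exons hold 0.474% against 13.9%.

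The sequence ATYGAT (Y is C or T), the core bound by proteins of the Onecut family, was present at many summits. It occurred in 2580 of 6747 summit windows (38.2%) and in 1353 of 13481 flanking windows (10.04%), an odds ratio of 5.55 (95% interval 5.15 to 5.98). Of its forms, ATCGAT had an odds ratio of 9.71 (8.62 to 10.9; 21.2% against 2.70%) and ATTGAT had 2.87 (2.63 to 3.13; 19.1% against 7.61%; Fisher's exact test, adjusted p = 2.4e-121). The share with ATYGAT was 36.6% at promoter summits (34.9 to 38.4), 40.9% in introns (39.0 to 42.9) and 35.7% outside protein-coding genes (32.9 to 38.6). Occurrences were concentrated at the summit itself. There were 1757 in the 40 bp within 20 bp of the 6747 summits and 621 in the 80 bp at 150 to 190 bp on both sides, a ratio per bp of 5.66. The ATYGAT odds ratio was 7.68 in the stronger 50% of peaks, 3.62 in wider windows and 2.98 over sub-threshold summits. Of the main list, 54.5% of peaks had the same width of 436 bp; ATYGAT was in 32.4% of these windows and in 45.2% of those of other peaks, whose median signal was 263.1 against 110.2.

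**Figure D2:**
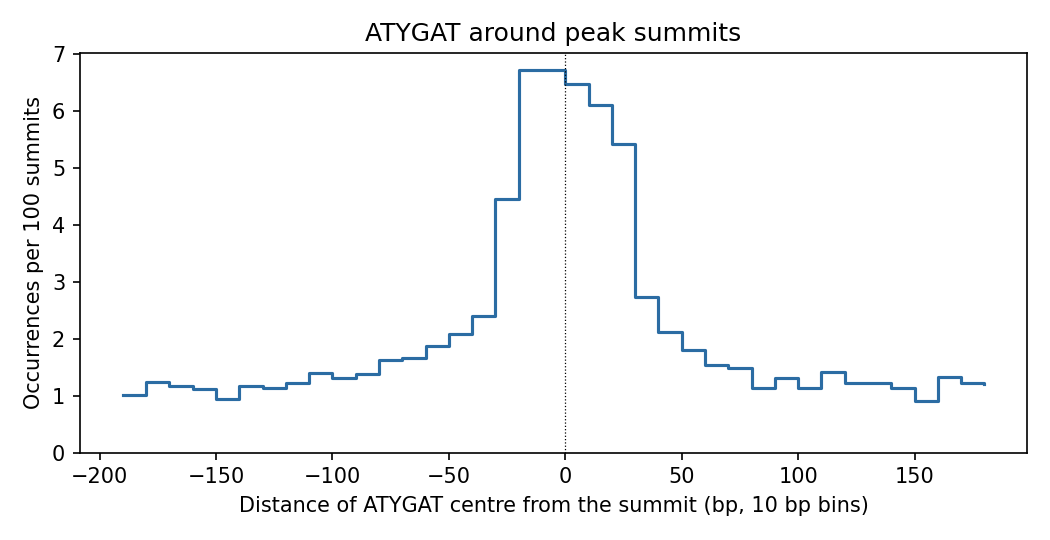
Number of ATYGAT occurrences per 100 summits (y axis) by distance of the motif centre from the summit in 10 bp bins (x axis, bp), over 6747 summits. The count is highest in the bins next to the summit, at 6.73 per 100 summits in each of the bins from -20 to -1 bp.

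Elements of other promoter-binding factors were also found. TATCGATA, the DNA replication-related element bound by DREF, contains ATCGAT and occurred in 121 summit windows (1.79%, against 0.193%; odds ratio 9.45, 6.18 to 14.5; Fisher's exact test, adjusted p = 5.2e-34). Its odds ratio was 4.84 without replicate 1 (1.86% against 0.391%) and 3.82 in the stronger 50% of peaks (1.90% against 0.504%). The summit share hardly changed in these lists and the flanking share rose, so these falls do not show weaker enrichment at summits. With other controls the odds ratio of TATCGATA was 3.72 (matched windows), 2.14 (sub-threshold summits) and 24.6 (shuffled windows). With all windows holding TATCGATA removed, ATCGAT still had an odds ratio of 9.57 (8.46 to 10.8), but that took out only 121 summit windows. Removing all windows with CGATA, the end of that element, left 482 of 5091 summit windows with ATCGAT (9.47%, against 1.60%). Its odds ratio was then 6.45 (5.43 to 7.65). GGTCACACT, a core promoter sequence known as Motif 1, was in 61 windows (0.904%, against 0.119%; odds ratio 7.68, 4.42 to 13.3; exact test, adjusted p = 4.1e-16). Its odds ratio was 4.66 without replicate 2 (0.860% against 0.186%) and 3.67 in the stronger 50% of peaks (0.919% against 0.252%). Here too the flanking share rose and the summit share hardly changed. The odds ratio of GGTCACACT was 2.08 against sub-threshold summits and 20.5 against shuffled windows. Smaller excesses by the exact test were found for GAGAG, the site of GAGA factor (odds ratio 1.32, adjusted p = 1.8e-10), the GATA sequence GATAA (1.32, adjusted p = 2.5e-14), the repeat CACACAC (1.34, adjusted p = 3.2e-05) and the E box CAGCTG (1.28, adjusted p = 0.00044). GATAA is part of the 6-mer CGATAA, which was in 9.99% of summit windows and 4.03% of flanking windows. The excess of GATAA thus does not show a separate GATA signal. TTGATC was less frequent than in flanks (0.769, exact test, adjusted p = 0.0013). The calls for CAGCTG and TTGATC ended with either replicate left out (odds ratios 1.15 and 1.13, and 0.894 and 0.902), in the stronger 50% of peaks (1.17 and 0.901), at an IDR of 0.001 (1.17 and 0.847) and in narrower windows (1.19 and 0.950). TTGATC had an odds ratio of 1.02 against sub-threshold summits. The call for CACACAC ended without replicate 2 (1.10), in narrower windows of 51 bp (1.16) and at an IDR of 0.001 (1.19), and the call for GAGAG ended against sub-threshold summits (1.07). Against those summits CACACAC was depleted (0.858, exact test, adjusted p = 0.016). Against shuffled windows the odds ratios were 3.39 for CAGCTG and 3.25 for CACACAC. The Zelda site CAGGTAG (0.718, exact test, adjusted p = 0.109) and the cAMP response element TGACGTCA (1.60, adjusted p = 0.116) did not pass. The result for TGACGTCA depended on the setting. It passed in 6 alternatives: the pooled list (2.67), narrower windows (2.75), wider windows (1.75), matched windows (2.11), shuffled windows (2.86) and sub-threshold summits (1.84), while without replicate 1 its odds ratio was 1.03.

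**Figure D3:**
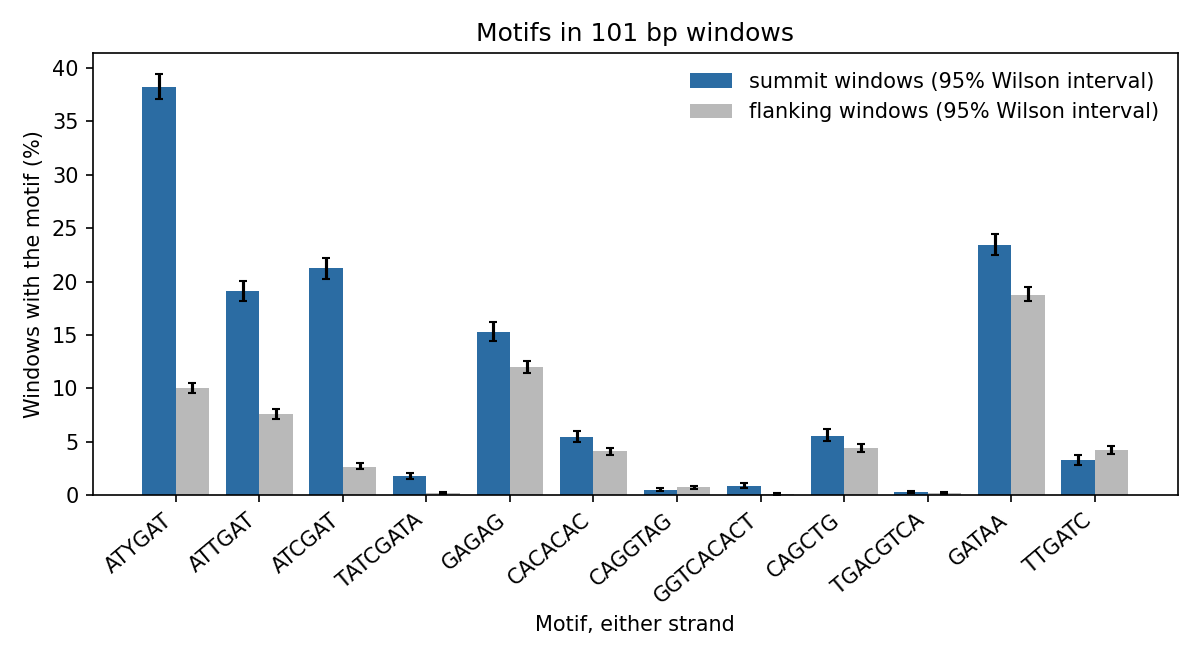
Share of windows that hold each of the 12 motifs on either strand, in percent, for 6747 summit windows (blue) and 13481 flanking windows (grey), with 95% Wilson intervals. ATYGAT is in 38.2% of summit windows and 10.04% of flanking windows, and GAGAG is in 15.3% and 12.02%.

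Among all 6-mers, 49 were enriched at summits and ATCGAT ranked at place 1 by odds ratio. It was followed by TATCGA (odds ratio 5.603, 5.01 to 6.27), AATCGA (3.66), TATTGA (3.43), CGATAG (3.28) and ATCAAT, the reverse complement of ATTGAT (2.87). ACACTG (2.30, 2.02 to 2.61; 7.78% against 3.55%), CGCTAG (2.10) and ACAGTG (1.91) were also among the 20 with the highest odds ratios. A further 162 6-mers were depleted by the same rule, led by GGATCC (0.333). With sub-threshold summits as controls, a choice made after seeing the data, 20 6-mers were enriched, 18 of them among the 49.

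The highest peaks lay at genes of varied function, and most held the motif. Of the 20 peaks of highest signal, 14 were at promoters and 17 had ATYGAT within 50 bp of the summit, and each had a signal at least 13.1 times the median of the list. The highest lay on chromosome 3L at 16712313 to 16712850, with its summit 472 bp downstream of a TSS of Dab, an adaptor protein of Abl kinase signalling. Its signal was 2942 in the main list, 1180 in the ranked list of replicate 1 and 1799 in that of replicate 2, and the sequence GAAAATCGATAATC was found at -19 bp. The peak at Dhpr, dihydropteridine reductase, on 3L at 9134316 to 9134758 had a signal of 2668 and held TCTTATTGATTTTC. The peak in bchs (2L, 5906934 to 5907719, signal 2440), which encodes an autophagy scaffold protein, held AAAAATCAATAAAA. A peak inside an intron of gpp, a histone H3 methyltransferase (3R, 6419105 to 6419535, signal 2426), held TTTTATCGATTTTG at 2 bp from the summit. Peaks at CaMKI, a calcium/calmodulin-dependent kinase (4, 445952 to 446411, signal 2359), and at capu, a formin (2L, 3895875 to 3896322, signal 2124), held GAAAATCAATAAAT and AAAAATCGATGGCA. A peak in the promoter of SoxN, a Sox factor of the early neuroectoderm, ranked 16 (2L, 8825118 to 8825598, signal 2023.5) and held GCGGATCGATATAG. The peaks at the promoters of Ugalt, a UDP-galactose transporter (X, 2703664 to 2704097, signal 2898), and of CG14100 (3L, 19590417 to 19590814, signal 2347) had no ATYGAT in the window, and neither had the peak nearest to cbt, a zinc finger factor (2L, 480878 to 481309, signal 1962), whose summit lay in an intron of ush. The other genes nearest to these 20 peaks were CG13293, CG30466, 14-3-3epsilon, CG11050, CG14442, CG15629, CG5746, spen, CG9368 and lute, with signals from 1950 to 2399.

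At the onecut gene itself (FBgn0028996, chromosome 4, 598555 to 607649, minus strand) no summit was found in the main list, the pooled list or the list of replicate 1, nor in their ranked lists. The list of replicate 2 held 1 peak there, at 607482 to 607917, with its summit 51 bp upstream of the TSS, a signal of 65.9 and an IDR of 0.00567, at rank 4668 of 6023 by signal. The genes with most summits were large loci. bun, which encodes TSC22-domain proteins, held 19 summits over 91072 bp (2L, 12455540 to 12546611), and kirre, a cell adhesion protein of myoblast fusion, held 18 over 394149 bp (X, 2740384 to 3134532). gpp (3R, 6406855 to 6449274) and ush, a cofactor of GATA factors (2L, 476220 to 540560), held 16 each, and CG1677 (X, 7281089 to 7405797) held 15. Counted per 10000 bp, gpp had 3.68 summits and kirre 0.456. In replicate 1 and replicate 2 alone, bun had 10 and 15 summits and CG1677 had 17 and 13.

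Genes for cytoplasmic ribosomal proteins stood out among the 16 gene lists. Of 92 such genes, 75 had a summit (81.5%), against 31.3% of the 13945 protein-coding genes (odds ratio 9.84, 5.81 to 16.7; Fisher's exact test, adjusted p = 4.2e-22). Draws matched on gene length gave a mean of 18.1 genes (permutation test, adjusted p = 0.0032, from the smallest p that 10000 draws allow). Their highest peaks were at the promoters of RpS27 (3R, 25247346 to 25247681, signal 799.9), RpL7 (2L, 10200891 to 10201208, 752.9), RpL14 (3L, 8600815 to 8601130, 623.3) and RpS4 (3L, 13041604 to 13041954, 589.8), and none of these 4 had ATYGAT in its window. Over all 76 summits at ribosomal protein promoters, 26 windows held ATYGAT (34.2%), against 1066 of 2904 at other promoters (36.7%; odds ratio 0.897, 0.555 to 1.45; Fisher's exact test, p = 0.718). TATCGATA, which contains ATCGAT, was in 17.1% and 3.48% of all these windows. Without them ATYGAT was in 13 of 63 (20.6%) and 965 of 2803 (34.4%; odds ratio 0.495, 0.268 to 0.916), a filter that takes away only windows with the motif. These 76 summits had a median signal of 299.4, against 158.4 at other promoters, a 1.89-fold difference (permutation test, two-sided, p = 0.0001, the smallest that 10000 permutations can give).

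Many genes of neurons carried a summit, and they are also long genes. A summit was found in 21 of 25 pan-neuronal and synaptic genes (84.0%; odds ratio 11.6, 3.97 to 33.8; Fisher's exact test, adjusted p = 6.0e-07) and in 19 of 24 axon guidance genes (79.2%; odds ratio 8.38, 3.13 to 22.5; adjusted p = 9.8e-06). Matched on gene length, the draws gave means of 15.8 and 15.9 genes, and neither list passed the permutation test (adjusted p = 0.312 and 0.543). Before adjustment over the 16 lists, these permutation p-values were 0.039 and 0.237. By promoter summits the odds ratios were 4.92 and 4.59, and among genes with a ranked peak they were 5.63 and 15.3. Neither list passed the length-matched permutation test in these settings (adjusted p = 0.242 and 0.262, and 0.310 and 0.172). With simulated summits placed uniformly, Fisher's exact test called 9 of the 16 lists and the matched test called 0. The real summits were not uniform, with 44.2% at promoters. That simulation therefore shows that length can produce such calls, not how many to expect here. Genes with a summit had a median length of 4341 bp and those without had 1755 bp. Among the neuronal genes with the highest peaks were Syt1, a calcium sensor of synaptic vesicles (2L, 2799888 to 2800241, signal 1142), Appl, the amyloid precursor-like protein (X, 530181 to 530582, signal 1138), elav, an RNA-binding protein used as a marker of neurons (X, 522245 to 522785, in an intron, signal 1083), and CadN, neural cadherin (2L, 17751309 to 17751666, in an intron, signal 892.8). All 4 had ATCGAT in the window. The highest peaks of the axon guidance list were in the netrin receptor gene fra (2R, 12540125 to 12540504, intron, signal 1013), Sema1a (2L, 8612030 to 8612348, intron, signal 722.9), trio (3L, 1034540 to 1034885, promoter, signal 564.1) and Dscam1 (2R, 7377512 to 7377808, 5' UTR, signal 491.7), and all 4 held ATYGAT.

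**Figure D4:**
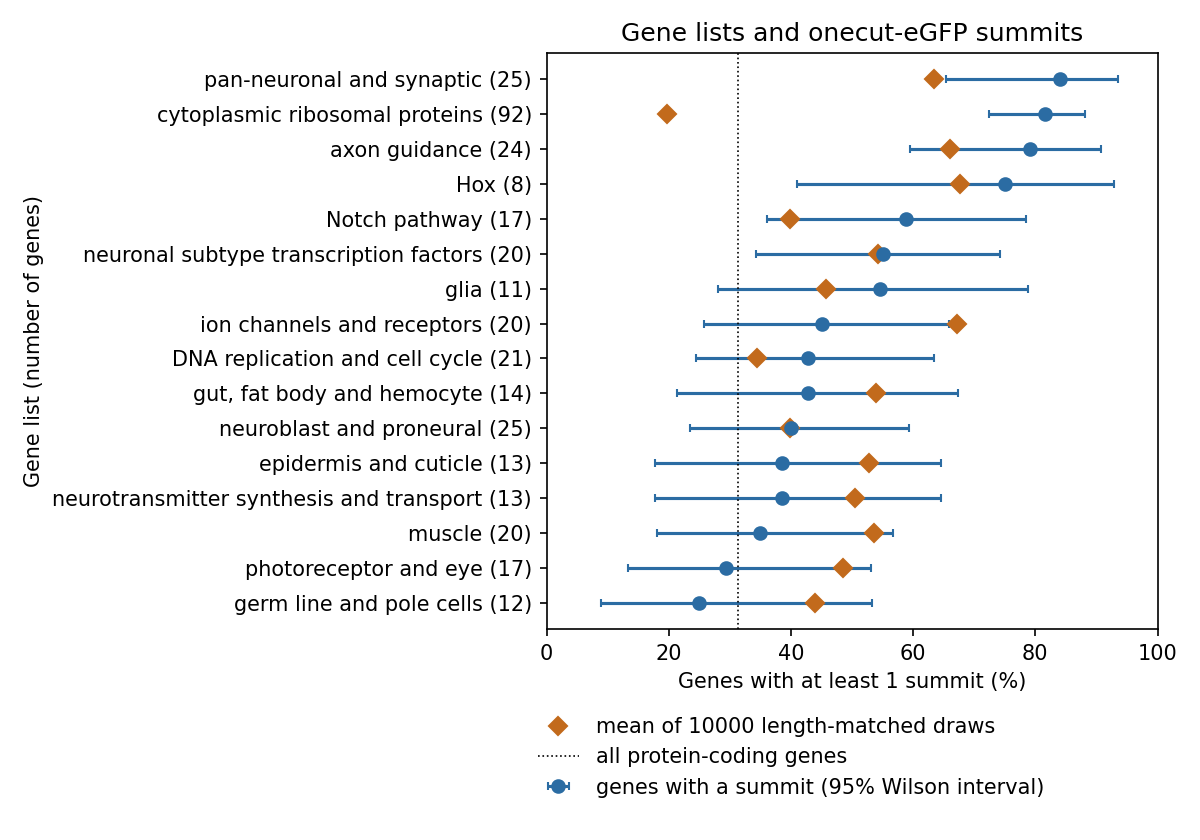
Share of genes with at least 1 summit in each of the 16 lists (blue points, 95% Wilson intervals), the mean of 10000 length-matched draws (orange diamonds) and the share of all protein-coding genes (dotted line, 31.3%), in percent. Ribosomal protein genes lie at 81.5% against a matched mean of 19.7%, while pan-neuronal genes lie at 84.0% against 63.3%.

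The other 13 lists did not pass Fisher's exact test or the matched test. Among developmental regulators, 6 of 8 Hox genes had a summit (Fisher's exact test, adjusted p = 0.0563), with the highest peaks in introns of abd-A (signal 842.0) and Abd-B (387.2). So did 10 of 17 Notch pathway genes (exact test, adjusted p = 0.0605), led by numb (423.9) and mam (378.6), and 11 of 20 transcription factors of neuronal subtypes (adjusted p = 0.0774), led by otp (911.9) and fkh (543.9). Of neuroblast and proneural genes, 10 of 25 had a summit (exact test, adjusted p = 0.567), led by SoxN and pros (342.8). Ion channels and receptors had 9 of 20 (exact test, adjusted p = 0.441; sei 780.5 and Ih 684.1) and genes of neurotransmitter synthesis and transport 5 of 13 (adjusted p = 0.690; Ddc 300.6 and ChAT 296.5). Among the remaining lists, glia had 6 of 11 genes (exact test, adjusted p = 0.251; moody 831.6 and pnt 285.2), photoreceptor and eye 5 of 17 (adjusted p = 1.00; norpA 644.1 and Rh5 503.0) and muscle 7 of 20 (adjusted p = 0.864; Mef2 491.0 and tin 436.5). Gut, fat body and hemocyte genes had 6 of 14 (exact test, adjusted p = 0.567; ush 1962 and hkb 1043), epidermis and cuticle 5 of 13 (adjusted p = 0.690; shn 424.0 and grh 324.7). DNA replication and cell cycle genes had 9 of 21 (exact test, adjusted p = 0.441; Dref 535.9 and CycB 260.0) and germ line and pole cell genes 3 of 12 (adjusted p = 0.864; vas 260.8 and piwi 182.3). The summit in vas also lay inside solo and vig, and it was not at a promoter of vas. Hox genes and neuronal subtype factors passed Fisher's exact test in the pooled list (odds ratios 14.7 and 3.15), and by nearest TSS so did these 2, Notch pathway genes and gut, fat body and hemocyte genes (18.0, 4.77, 3.67 and 4.62). Without replicate 2 the odds ratio of Notch pathway genes fell from 3.14 to 1.54, and without replicate 1 that of Hox genes fell from 6.60 to 2.50. By promoter summits Notch pathway genes passed Fisher's exact test (3.69, adjusted p = 0.0315). None of these calls passed the length-matched permutation test in the same setting (adjusted p = 0.751 and 0.919 in the pooled list, 0.428, 0.428, 0.316 and 0.543 by nearest TSS, and 0.20 by promoter summits).

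Strong peaks were more often promoter peaks and more often held the motif. In the top 25% of peaks by signal, 914 of 1686 were at promoters (54.2%), against 681 of 1686 in the bottom 25% (40.4%; odds ratio 1.75, 1.52 to 2.00; Fisher's exact test, adjusted p = 1.1e-15). ATYGAT was in 869 windows of the top group (51.5%) and 478 of the bottom group (28.4%; odds ratio 2.69, 2.33 to 3.10; exact test, adjusted p = 6.0e-43).

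Summits were spread over all arms. The X held 46.6 summits per Mb and the autosomal arms 2 and 3 together held 51.4, a ratio of 0.907 (0.850 to 0.968; permutation test, adjusted p = 0.0076). Per TSS the ratio was 0.946 and did not pass the permutation test (adjusted p = 0.185). Chromosome 4, where onecut lies, held 54 summits, 40.6 per Mb (ratio 0.789, 0.604 to 1.03; permutation test, adjusted p = 0.083), and per TSS its ratio was 1.08. With replicate 2 left out it passed the permutation test, at a ratio of 0.617 (adjusted p = 0.0068).

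Of the small RNA genes, those for spliceosomal and related snRNAs were near summits more often than shuffled positions. A summit lay within 250 bp of 6 of 32 snRNA genes (18.8%, against 3.40%; permutation test, adjusted p = 0.01). These were U1 at 21D and 95Ca, U2 at 34ABb, U4 at 39B, U5 at 63BC and 7SK, named here after their values were seen. The call was lost for the stronger 50% of peaks (6.25%), at an IDR of 0.001 (12.5%, permutation test, adjusted p = 0.09) and at a distance of 1000 bp (21.9%), where snoRNA genes passed (26.8%, permutation test, adjusted p = 0.01). Summits were near 11 of 290 tRNA genes, 12 of 269 snoRNA genes and 11 of 260 miRNA genes, none past the test (adjusted p = 0.504 for each by permutation), and near 0 of 99 rRNA genes (adjusted p = 0.504).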

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

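The test of sub-threshold summits was chosen after seeing the data, as were all tests of explanations here except the one with shuffled windows.

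A motif signal was present in peaks below the threshold, which the report used as a control and in comparing the replicates. Of the 25472 ranked summits that did not pass the authors' threshold, 17.2% had ATYGAT, against 10.2% of their own flanking windows (odds ratio 1.83, 1.75 to 1.91; Fisher's exact test, adjusted p = 6.5e-159). The share was 24.7% for the 4267 summits with an IDR from 0.01 to 0.1 and 15.7% for the 21205 above 0.1, beside 38.2% past the threshold. Promoters held 35.2% and 18.9% of the summits in these ranges, and coding exons held 1.01% and 4.72%.

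For ATYGAT at the summits of the main list, 3 technical explanations were weighed. With all windows that hold CGATA removed, the sequence in the sites of DREF and of the insulator protein BEAF-32, ATYGAT kept an odds ratio of 4.25 (3.89 to 4.63), which argues against those elements as the whole source. Base composition is argued against by an odds ratio of 4.95 over dinucleotide-shuffled windows. Over sub-threshold summits the odds ratio was 2.98, so the motif was not equally frequent in all called regions. That control cannot decide on a property of stronger regions. Fewer of its summits were at promoters (21.7% against 44.2%), and TATCGATA (2.14, 1.71 to 2.67) and GGTCACACT (2.08, 1.52 to 2.85) also exceeded it. Occurrences per bp were 5.66 times as frequent within 20 bp of the summit as at 150 to 190 bp, which is consistent with direct contact of the tagged protein with the motif, as a hypothesis. Other proteins that bind the same sequence, and the accessibility of the regions, stay open, since neither was measured here and 1 group gives no biological contrast.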

How the results depend on the processing

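The stricter IDR, sub-threshold controls and the ranked-peak background were chosen after seeing the data. Promoter excess (2.65 to 5.56), the ATYGAT odds ratio (2.98 to 7.68), replicate overlap and both signal comparisons kept their direction and stayed past the threshold in every alternative run, and ATCGAT stayed at rank 1 of the 6-mers where they were counted. A planned cut at an IDR of 0.01 changed little (6772 peaks), since the lists already stop there, so the stronger 50% of peaks served as the stricter list. Read depth is unknown, and no statement on it can be made. No paired analysis was possible because there is 1 group. For the results that did not hold, the cause was not tested, except that the length-matched test removes gene length by construction.

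At an IDR of 0.001 the main list fell to 3977 peaks and the ratios were 1.12 for single replicates and 1.15 for pooled data. Spearman rho and Pearson r were 0.796 and 0.918 for peaks past the threshold, and 0.681 and 0.837 for the top 1000 peaks. The enriched 6-mers numbered 74 against matched windows and 20 against sub-threshold summits. Lists past the threshold numbered 5 in the pooled list, 7 by nearest TSS and 1 matched on gene length. Chromosome 4 passed the test with ratios of 0.753 (pooled list) and 0.691 (IDR of 0.001), ranged from 0.617 to 0.763 with a replicate left out, and turned to 1.08 per TSS, where the X ratio of 0.946 lost its call. No snRNA call was left (0 classes) for the stronger 50% of peaks or at an IDR of 0.001.

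Directions turned as follows. Introns went to 1.03-fold with a 250 bp promoter. 5' UTRs went to 0.614-fold with a 1000 bp promoter and an odds ratio of 0.757 against sub-threshold summits. CAGGTAG went to 1.39 against shuffled windows. Against sub-threshold summits CACACAC had 0.858, CAGGTAG 1.13 and TTGATC 1.02. Among lists without a call, germ line went to 1.05 in the pooled list. With a replicate left out, neuroblast ranged from 0.536 to 1.18, photoreceptor from 0.770 to 1.17 and germ line from 0.834 to 1.41. In the stronger 50% of peaks neuroblast had 0.757 and DNA replication 0.663, and at an IDR of 0.001 neuroblast had 0.668. By promoter summits, ion channels and neuronal subtype factors had 0.818 each, epidermis 0.594 and Hox 0.467. By nearest TSS, photoreceptor had 1.40 and DNA replication 0.603. Matched on gene length, observed over expected was 0.761 for neurotransmitter genes, 0.670 for ion channels, 0.652 for muscle, 0.796 for gut and 0.728 for epidermis. Among genes with a ranked peak these 5 had 0.667, 0.801, 0.467, 0.801 and 0.801, DNA replication 0.901 and germ line 1.202. With summits inside genes, tRNA had 0%, snoRNA 0.372% and miRNA 0.385%.

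Among the other comparisons of single classes, motifs, lists and named genes, 519 kept direction and call or count, 16 gained a call, 19 lost one and 45 counts of summits in named genes moved by over 1.5 times. Of 61 named genes, 59 had a summit in the main list and 59 to 60 in the alternatives. Nearly all were named for their peaks in the main list, so this count follows from the naming rule and does not measure stability.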

Other observations

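Gene families beyond the lists were picked by symbol after seeing the data, as were the test of the motif flank and the tests of explanations given here, except that the length-matched draws were planned. Of 20 families, 3 had more genes with a summit than length-matched draws and 5 had fewer (permutation test, two-sided, adjusted over the 20). Summits were found at 25 of 73 mitochondrial ribosomal protein genes (matched mean 11.6, permutation test, adjusted p = 0.00067), 16 of 33 V-ATPase subunits (8.63, adjusted p = 0.0145) and 8 of 15 ATP synthase subunits (2.90, adjusted p = 0.012). Without matching on length, Fisher's exact test called none of these 3 (adjusted p = 0.817, 0.0861 and 0.152). Among the 5 families with fewer, a summit was found at 1 of 59 odorant receptor genes (13.4), 1 of 60 gustatory receptor genes (13.7), 1 of 60 ionotropic receptor genes (17.2), 2 of 71 CPR cuticular protein genes (15.4) and 4 of 85 cytochrome P450 genes (24.2), each with an adjusted p of 0.00067. The other 12 families did not pass the matched test, though without matching Fisher's exact test called fewer histones (odds ratio 0.180, adjusted p = 1.5e-08), larval cuticle proteins and Jonah proteases (adjusted p = 0.0119 each). The 12 were proteasome subunits (10 of 48), translation factors (22 of 52), respiratory complex I (13 of 40), complexes III and IV (9 of 25), aminoacyl-tRNA synthetases (9 of 17), Rab GTPases (17 of 36), chaperonin CCT (3 of 8), MCM helicase (2 of 6), spliceosomal proteins (7 of 22), histones (9 of 118), larval cuticle proteins (0 of 15) and Jonah proteases (0 of 16). Histone genes are multicopy and may share reads, which was not tested.

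A flank of the motif was tested on the same windows in which it had been noticed, so the test is descriptive. ATTGAT was followed by TTT in 38.3% of 1320 occurrences at summits and in 6.49% of 1033 in flanking windows (odds ratio 8.96, 6.83 to 11.8; Fisher's exact test, adjusted p = 2.5e-79). For ATCGAT it was 14.5% of 3182 readings against 3.47% of 720, where each site counts 2 times because it reads the same on both strands.

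For ribosomal protein genes, gene length was not a possible source of the excess. Draws matched on length gave 18.1 genes (19.7%), below the 31.3% of all protein-coding genes, and 75 had a summit. Length alone thus predicts fewer genes, and the matched test says nothing more on the cause. ATYGAT was in 34.2% of the 76 summit windows at their promoters and in 36.7% of 2904 at other promoters, an odds ratio of 0.897 (0.555 to 1.45), so whether their signal arises without the Onecut motif, as background of highly transcribed promoters could, was not decided. TATCGATA, which contains ATCGAT, was in 17.1% and 3.48% (odds ratio 5.73, exact test, adjusted p = 1.1e-05). Without those windows the odds ratio of ATYGAT was 0.495 (0.268 to 0.916), but taking them away lowers the share more at ribosomal protein promoters by construction, so this decides nothing by itself. No control track was analysed here, and no biological explanation was tested.

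For the neuronal lists, gene length could account for much of the excess, and whether for all of it was not decided. The length-matched test gave adjusted p-values of 0.312 for pan-neuronal and synaptic genes and 0.543 for axon guidance genes, with matched means of 63.3% and 66.1% of genes beside 84.0% and 79.2% observed. Before adjustment over the 16 lists, the permutation p of pan-neuronal and synaptic genes was 0.039. Across the alternatives it lay between 0.0114 (IDR of 0.001) and 0.097 (genes with a ranked peak). The lowest adjusted p of that list was 0.0912, so it passed in no setting. Ion channels and receptors went the other way, with 9 genes against a matched mean of 13.4. Their length-matched permutation p before adjustment was 0.0598, and 0.0134 by nearest TSS. A smaller excess over long genes in general is not excluded by lists of 25 and 24 genes. No biological explanation was tested.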
